A study of Mus musculus with 12 samples.

How the data were processed

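The progenitor line gave 12 ChIP-seq libraries: 8 of H3K4me1 (4 groups of 2 biological replicates), 3 of H3K4me3 (1 each for HPC, 120 h B cells and myeloid cells) and 1 input of uninduced HPC. Per the labels' protocols, HPC grew with IL7, Flt3L and SCF on S17 stromal cells. B-cell differentiation used IL-7 and SCF with doxycycline on S17 cells or, alternatively, alpha-MEM on Tst-4 stromal cells, and the labels do not say which library had which. Myeloid cultures had IL3, Flt3L, GM-CSF and M-CSF. The labels give an H3K4me1 antibody lot for replicate 2 and none for replicate 1.

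The deposited files hold counts: each line gives a position and strand and the number of 30 bp reads there, and no normalization was found in them. CASAVA, Bowtie, HOMER and the build mm8 are named, per the submitters' processing notes, with no versions, roles or parameters. No position and strand was listed more than once (0 in every file). From 1.60% (HPC H3K4me1 replicate 2) to 9.59% (120 h H3K4me3) of the reads repeated a position and strand already seen.

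A single read per position and strand was kept on 21 chromosomes (19 autosomes, X and Y), which left 9047195 to 22389585 reads per library. Each read was moved 75 bp towards the fragment middle and counted in windows of 500 bp. H3K4me1 regions were windows whose mean over the 8 libraries was at least 2-fold above both the input, averaged over 2 further windows on each side, and the genome mean of windows with reads. Windows at most 1 window apart were merged, which gave 97642 regions, and those with a mean of at least 10 reads per library were tested (82320, median width 1500 bp). H3K4me3 regions were built in the same way at 4-fold over the 3 libraries (16447 regions). H3K4me1 regions 3 kb or more from an H3K4me3 region were called distal (59307) and the others proximal (23013). Region sets per group needed 4-fold in both replicates.

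H3K4me1 was tested by edgeR's quasi-likelihood test on the read counts of all 8 libraries with TMM factors over the tested regions, in 5 comparisons, with Benjamini-Hochberg adjustment and a threshold of 0.05. The SE of a log2 change is its size divided by the square root of F. CPM values are reads per library size, TMM-scaled. H3K4me3, with 1 library per group, was compared by ratios scaled to the reads inside regions (4279368 in HPC, 4811923 at 120 h and 3840415 in myeloid cells), called at 2-fold or more with an exact conditional binomial interval of 95% excluding 1. These intervals, and those of ratios from few H3K4me1 reads, cover counting error only. The libraries were amplified by PCR, so reads are not fully independent. Distal regions were linked to the nearest H3K4me3 region within 100 kb and tested by Fisher's exact test.

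The design, the alternatives and the rule for naming regions were written before the data were examined. Named for each H3K4me1 comparison were the 5 distal and 3 proximal regions with the largest log2 change in each direction among those past the threshold that moved alike in both replicates. Where the test without a block called none, the rule was applied to the test with it. For H3K4me3 it named the 5 largest ratios in each direction with at least 50 reads in the higher library. Not every region it picked is given in the text. Gene lists were planned only for an annotation of the files' build. The table at hand is of GRCm38.p6 while the files use mm8, so no gene list was used.

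Replicate numbers were checked for pairing before the calls were compared. Across the 6 pairs of groups, the differences between replicate 1 and replicate 2 correlated at r = 0.246 (48 h and myeloid) to 0.423 (HPC and myeloid), above the limit of 0.1, and the 2nd principal component (17.8% of variance) separated the numbers. The numbers were therefore used as a block in a further test, on the evidence of the data. The planned main test has no block and so ignores this pairing. It gives the counts, named regions and odds ratios below unless the block is stated. The titles of all replicate 2 H3K4me1 libraries carry the tag .new, which no replicate 1 title has. The labels do not say what the tag stands for and name no shared day or batch. The common biological coefficient of variation was 0.192 without and 0.106 with the block. Replicates correlated at r = 0.933 (HPC), 0.939 (48 h), 0.925 (120 h) and 0.920 (myeloid).

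Both tests were tested on simulated data with changes planted in 120 h against HPC, 100 regions per fold among 82320. Without the block, 8% of 2-fold and 75% of 4-fold changes were recovered with 3 false calls. With it, 42% and 95% were recovered with 4. Each test saw only data drawn from its own model and its own common spread. A replicate effect and the smaller spread were built in for the test with the block. The recoveries are therefore not compared on the same data, and they do not check the rate of false calls in the real libraries. The H3K4me3 intervals held the true ratio in 95.6% of 5000 simulated regions. These were drawn with counting error alone and known scale factors, so variation between libraries was not checked. Most simulated 2-fold changes of H3K4me1 were thus missed, and depth was not varied in this simulation.

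Alternatives were scaling by library total or by TMM over 239177 background bins of 10 kb, DESeq2, no filter, all reads kept, no shift, windows of 1000 bp, stricter thresholds, the 2 compared groups only, thinning to the smallest library, the block, and leaving out each library. Overlaps of changes against the shared HPC libraries were set against 10 simulations in which no group changed (for H3K4me3, with counting error alone, a simulation added after the data had been seen), and clusters of regions in blocks of 500 kb against 1000 permutations within chromosomes. No column of the sample table was left unused, and no library was left out of the comparisons. Software was edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 on R 4.3.3, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.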

Results

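H3K4me1, a mark found at enhancers and around promoters, and H3K4me3, a mark of active promoters, were profiled by ChIP-seq in a mouse hematopoietic progenitor line that carries a human ID2 transgene (Id2-HPC, here HPC). The design asks whether the enhancer mark and the promoter mark move together when these progenitors differentiate. Uninduced HPC (0 h) were compared with cells kept 48 h or 120 h under B-cell conditions, where the 120 h cells were CD19+, and with cells kept under myeloid conditions. No time under myeloid conditions is listed for the myeloid libraries. H3K4me1 was measured in 4 groups of 2 biological replicates each. H3K4me3 was measured in 1 library each of HPC, 120 h B cells and myeloid cells, and 1 input library came from HPC. The libraries held from 9457177 reads (input) to 22793678 reads (48 h H3K4me1, replicate 2). The H3K4me1 libraries of replicate 1 held 10162929 to 11548803 reads and those of replicate 2 held 20764873 to 22793678, so replicate 2 carries the smaller counting error. Of the reads used, 36.3% to 56.6% fell in H3K4me1 regions in the 8 H3K4me1 libraries, against 12.9% in the input. H3K4me3 regions took 38.1% to 48.4% of the reads of the H3K4me3 libraries and 2.04% of the input. All coordinates are on the mouse build mm8, and regions are named by coordinates because no gene annotation of that build was used here.

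At a fixed enrichment of 4-fold in both replicates, HPC held 39906 H3K4me1 regions, 48 h B-cell cultures 48519, 120 h B cells 33724 and myeloid cells 39383. Of the 120 h regions, 61.1% overlapped an HPC region and 76.6% overlapped a 48 h region. Of the myeloid regions, 65.5% overlapped an HPC region and 46.3% overlapped a 120 h region. The 48 h set was the largest and 48 h replicate 1 had the highest share of reads in regions (56.6%). These counts depend on the enrichment of each library and carry no test. At 8-fold, the sets shrank to 5290, 11512, 5667 and 5623 regions, and the overlaps of 120 h with HPC, myeloid with HPC and myeloid with 120 h regions fell to 35.0%, 42.9% and 27.9%.

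In CD19+ cells at 120 h, the distal region chr8:90666001-90669500 (3 kb or more from any H3K4me3 region) rose from 0.895 ± 0.731 CPM to 17.9 ± 1.81 CPM of H3K4me1 (TMM-scaled read rate per library; SD, n = 2 each) over HPC. This is a log2 change of 4.58 (SE 0.42; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.000402), while the region stood at 1.56 ± 0.286 at 48 h and 0.905 ± 0.079 in myeloid cells. At chr18:21819501-21820500 the log2 change was 4.53 (SE 0.58) and at chr3:52423501-52424500 it was 4.62 (SE 0.61). The regions chr3:136237501-136238000 and chr10:62108501-62109000 held 3 reads each over the HPC libraries and rose 29.9-fold (95% counting interval 9.84 to 148) and 24.8-fold (8.10 to 123). Among proximal regions (under 3 kb from an H3K4me3 region), 3 neighbouring ones on chromosome 8 rose together. They were chr8:124322501-124326500 (log2 3.94, SE 0.56), chr8:124327501-124331000 (log2 3.96, SE 0.40) and chr8:124348001-124349000 (log2 4.35, SE 0.49). Losses at 120 h included the proximal chr3:135526501-135530000, which fell from 10.1 ± 0.234 to 1.52 ± 0.436 CPM (log2 -2.82, SE 0.34, adjusted p = 0.000980, edgeR), and chr7:128205501-128206500 (log2 -3.09, SE 0.48). The distal regions that fell most held 1 to 3 reads over both 120 h libraries. Their ratios of HPC to 120 h were 25.4 at chr11:49794501-49795000 (4.23 to 1038), 17.0 at chr9:95986501-95987000 (4.40 to 145) and 14.7 at chr11:86965501-86966500 (4.76 to 73.6). They were 14.4 at chr13:95263001-95263500 (3.70 to 124) and 13.6 at chr12:112241501-112242000 (3.46 to 117), and 9.04 at the proximal chr7:30294001-30294500 (2.83 to 46.2).

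Of 82320 H3K4me1 regions, 5100 were higher and 4285 lower at 120 h than in HPC (edgeR, adjusted p under 0.05). With the replicate number as a block these counts were 11038 and 11140, and they included all of the former. Of 59307 distal regions 4216 rose and 3930 fell (median log2 changes among those called 1.54 and -1.44), a direction that turned to 8352 against 9986 with the block and to 2037 against 4305 when libraries were scaled by their total reads. Of 23013 proximal regions 884 rose and 355 fell, a direction that turned to 161 against 335 under library-total scaling. That scaling gave 2198 higher and 4640 lower regions of both kinds. Scaling on background bins gave 0 and 0 (edgeR; 1525 and 5565 at an unadjusted p under 0.05), against 3772 and 2598 by DESeq2 with its own scaling. The biological coefficient of variation was larger on background bins (0.446 against 0.192), so these 0 calls do not show that no region changed. The counts fell to 694 and 650 without HPC replicate 2, to 1012 and 158 without 120 h replicate 2, to 2690 and 1608 without HPC replicate 1 and to 3293 and 2767 without 120 h replicate 1. With the block they fell to 2835 and 2507 without HPC replicate 2 and to 4526 and 2436 without 120 h replicate 2. Each of the 16 regions the rule named here lost its call under background scaling without the block, and 15 of them passed under that scaling with it. These 16 were picked for the largest changes. Over all 82320 regions, background scaling with the block left 134 higher and 40 lower. Library-total scaling with the block gave 4796 and 12729. DESeq2 called 9 of the 16.

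**Figure D1:**
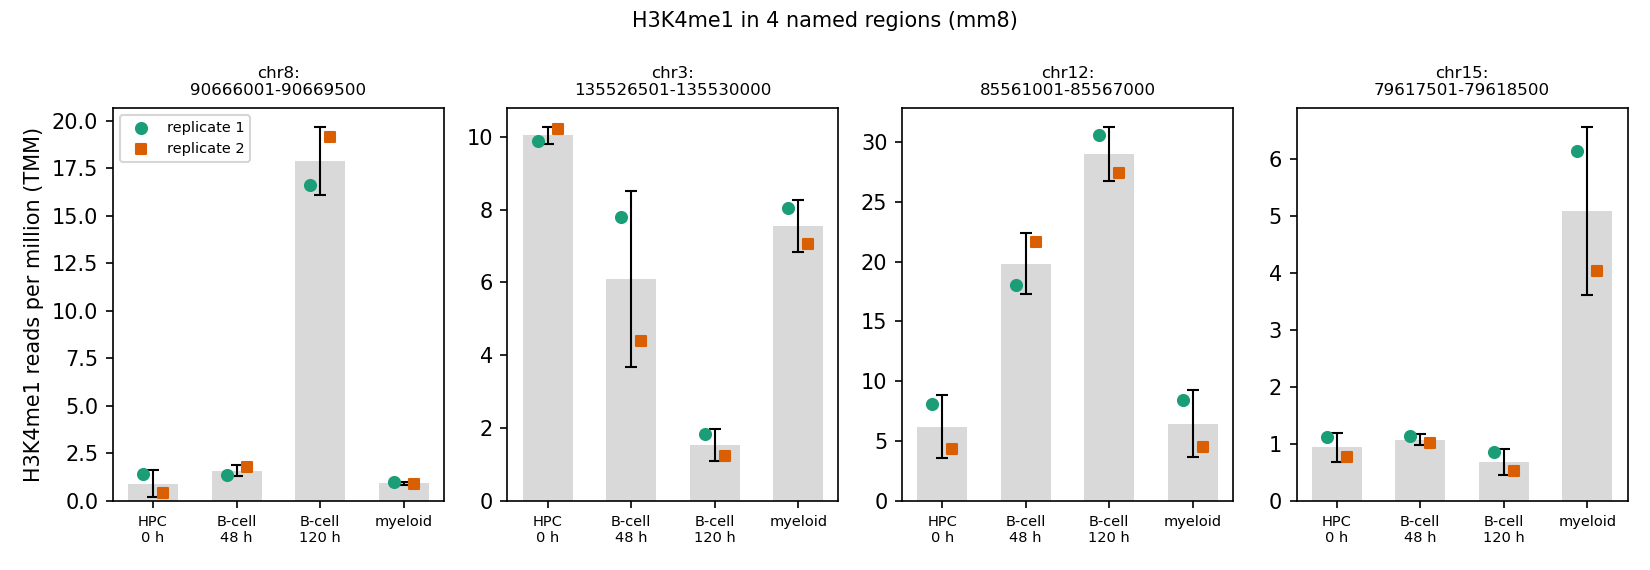
H3K4me1 CPM (TMM-scaled, linear y axis from 0) in 4 named regions for the 4 groups; bars are means, error bars SD (n = 2), circles replicate 1 and squares replicate 2. At chr8:90666001-90669500 the 120 h mean was 17.9 against 0.895 in HPC, at chr3:135526501-135530000 it was 1.52 against 10.1, at chr12:85561001-85567000 the 48 h mean was 19.8 against 6.20, and at chr15:79617501-79618500 the myeloid mean was 5.08 against 0.933.

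H3K4me3 was compared between 1 library of 120 h B cells and 1 of HPC, so the ratios below compare these libraries, and their intervals cover counting error only. At chr9:107183501-107186000 the 120 h library held 378 reads against 9 in HPC, a ratio of 37.4 (95% counting interval 19.5 to 82.3) after scaling to reads in regions. At chr8:124351001-124354000, next to the chromosome 8 regions that gained H3K4me1, it held 373 against 13 reads, a ratio of 25.5 (14.7 to 48.4). At chr16:17894001-17895500 it held 129 against 5 reads, a ratio of 22.9 (9.58 to 71.9). The region chr12:115855501-115857000 held 83 reads against 1 (ratio 73.8, 12.9 to 2950). The region chr13:54381501-54382000 held 55 reads against 0 in the HPC library (lower limit of the 95% counting interval of the ratio 12.8). In the other direction, chrX:38669001-38670000 held 56 reads in HPC and 1 at 120 h (ratio 63.0, 10.8 to 2531). HPC exceeded 120 h 18.9-fold (10.8 to 36.1) at chr1:137615501-137617500, 18.0-fold (6.69 to 68.0) at chr2:78866501-78868000, 12.3-fold (7.10 to 23.0) at chr16:45529501-45531500 and 10.8-fold (5.94 to 21.5) at chr5:23838501-23839500. Of 16447 H3K4me3 regions, 310 were higher and 867 lower at 120 h by 2-fold or more with an interval excluding 1. Scaled by all reads of the library, the split was 416 and 668.

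At 48 h under B-cell conditions, without a block, edgeR called 0 higher and 0 lower of 82320, with 2444 and 1368 at an unadjusted p under 0.05, and DESeq2 called 2 and 0. With the replicate number as a block, edgeR called 305 higher and 29 lower. The proximal chr12:85561001-85567000 rose from 6.20 ± 2.64 in HPC to 19.8 ± 2.56 at 48 h and 29.1 ± 2.27 at 120 h (log2 1.80 at 48 h, SE 0.21, edgeR adjusted p = 0.000459 with the block). Its neighbours chr12:85568001-85571000 (log2 1.73, SE 0.31) and chr12:85584001-85586000 (log2 1.79, SE 0.37) rose with it. Distal gains were chr14:30123501-30124000 (log2 3.03, SE 0.65), chr4:144634001-144635000 (log2 2.74, SE 0.57), chr12:99520501-99522500 (log2 2.35, SE 0.37), chr4:111312501-111318000 (log2 2.27, SE 0.37) and chr5:125304501-125306000 (log2 2.25, SE 0.38). The last stood at 4.02 ± 0.553 CPM at 48 h and 2.17 ± 0.288 at 120 h. Named losses had log2 changes from -2.16 (SE 0.46, chr14:121265001-121265500) to -2.00 (chr11:3223001-3223500), with chr11:3586001-3587000, chr11:120782501-120783500 and chr19:16405001-16406000 between them. Of the 305 gains 250 were distal and 55 proximal, and all 29 losses were distal. The edgeR adjusted p without a block was 1.00 for each of these 13 named regions, of which DESeq2, also without a block, called 1.

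The 48 h counts with the block depended on single libraries: they were 0 and 0 without HPC replicate 2, 105 and 4 without HPC replicate 1, 2218 and 364 without 48 h replicate 1, and 74 and 65 without 48 h replicate 2. They were also 27 and 0 without 120 h replicate 1 and 51 and 3 without 120 h replicate 2. With the block and library-total scaling, 392 regions were higher and 8 lower, and with background scaling 0 and 0 (edgeR; 3759 and 7 at an unadjusted p under 0.05).

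Between 48 h and 120 h, 3 of the 5 distal regions that gained most lay in one stretch of chromosome 18. They were chr18:21818001-21818500 (log2 4.33, SE 0.62), chr18:21826501-21827500 (log2 4.25, SE 0.49) and chr18:21819501-21820500 (from 0.294 ± 0.095 to 5.02 ± 0.540 CPM, SD, n = 2, edgeR adjusted p = 0.00354). The distal chr8:83876001-83876500 (log2 4.25, SE 0.63) and chr17:72491501-72492500 (log2 3.84, SE 0.49) also rose, as did the proximal chr5:143582001-143582500 (log2 3.48, SE 0.48) and chr8:124353001-124354000 (log2 3.04, SE 0.52). The proximal chr7:128205501-128206500 (log2 -2.72, SE 0.48), chr1:36496501-36498000 (log2 -2.07, SE 0.43) and chr3:135526501-135530000 (log2 -2.07, SE 0.35) fell. So did the distal chr2:17768001-17769000 (log2 -3.07, SE 0.70) and chr14:59325001-59325500 (log2 -2.96, SE 0.66). Of 82320 regions 1809 were higher and 1441 lower (edgeR), and with the block 6978 and 7257. Scaled by library total they were 686 and 4936, and scaled on background bins 0 and 0 (edgeR; 226 and 17410 at an unadjusted p under 0.05), against 1408 and 1212 by DESeq2, which called 7 of the 16 regions the rule named. Each of the 16 lost its call under background scaling without the block, and 15 passed under that scaling with it. Over all 82320 regions, the near-even split with the block became one-sided under other scalings. It was 53 and 4282 on background bins and 2055 and 15365 by library total. The counts were 22 and 3 without 48 h replicate 1, 49 and 1 without 120 h replicate 2 (15 of the 16 regions the rule named lost their call in either case) and 762 and 470 without 120 h replicate 1. With the block they were 1574 and 1095 without 120 h replicate 2 and 4155 and 4232 without 120 h replicate 1.

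**Figure D2:**
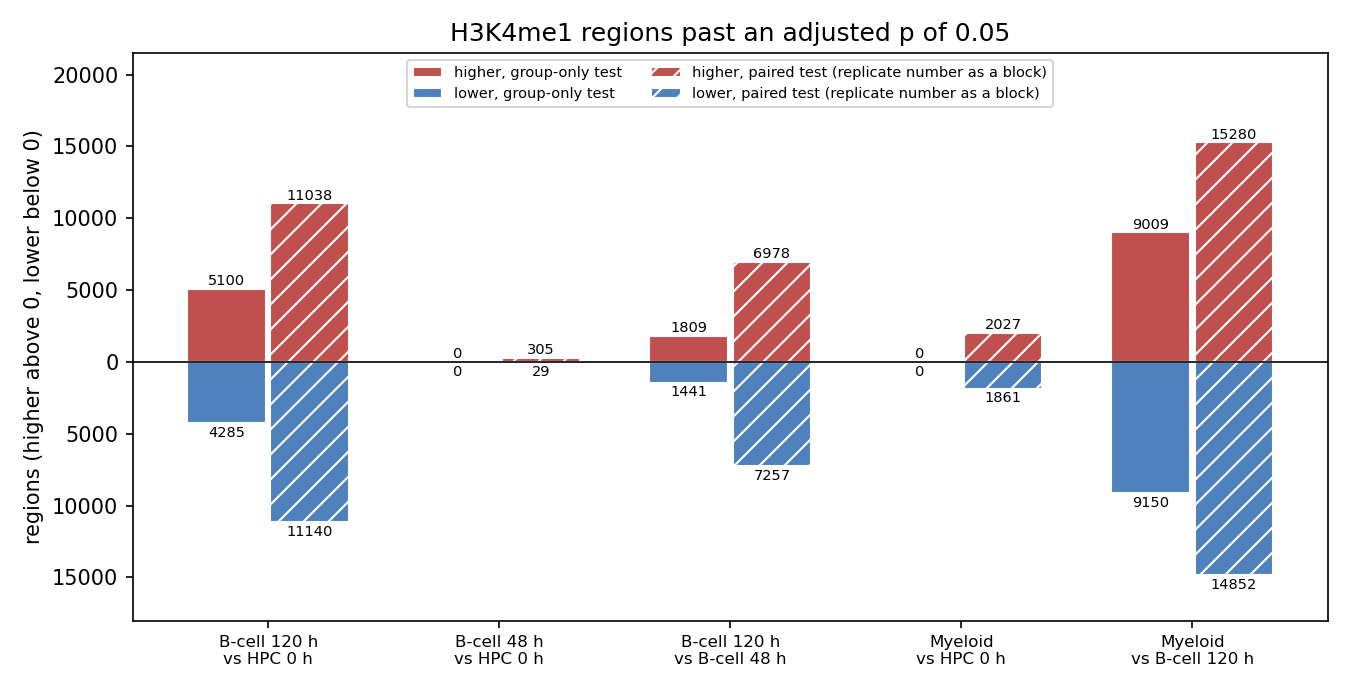
Number of H3K4me1 regions (y axis) past an adjusted p of 0.05 in each of 5 comparisons (x axis), higher above 0 and lower below 0, for the edgeR test on groups (plain bars) and with the replicate number as a block (hatched bars). For 48 h against HPC and myeloid against HPC the plain bars stand at 0 and the hatched bars at 305 and 29 and at 2027 and 1861.

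In myeloid cells against HPC, without a block, edgeR called 0 H3K4me1 regions higher and 0 lower on all 8 libraries, with 4319 and 4291 at an unadjusted p under 0.05. DESeq2 called 41 and 74 among the 26460 regions to which it gave an adjusted p. With the block, 2027 were higher and 1861 lower. The distal chr15:79617501-79618500 stood at 5.08 ± 1.48 CPM in myeloid cells against 0.933 ± 0.249 in HPC (log2 2.43, SE 0.31, adjusted p = 0.000188 with the block and 0.113 without, edgeR). Further gains with the block were chr17:64732001-64732500 (log2 2.76, SE 0.51), chr14:15843501-15844000 (log2 2.62, SE 0.52), chr17:5455001-5455500 (log2 2.43, SE 0.64) and chr14:8932501-8933000 (log2 2.42, SE 0.51). The proximal chr11:118230501-118231000 (log2 1.90, SE 0.44), chr4:122501001-122501500 (log2 1.88, SE 0.52) and chr4:154509001-154509500 (log2 1.88, SE 0.42) also rose. The proximal chr8:99048001-99051000 fell from 5.44 ± 0.697 to 2.08 ± 1.14 CPM (log2 -1.64, SE 0.28), as did chr10:87930001-87931000 (log2 -1.83, SE 0.46) and chr11:100962501-100963500 (log2 -1.50, SE 0.37). The distal chr16:37203001-37204000 fell too (log2 -3.01, SE 0.56). At chr1:191544001-191544500, chr12:71527001-71527500, chr1:188026001-188026500 and chr3:20334001-20334500 the myeloid libraries held 2 or 3 reads, and HPC exceeded them 10.9-fold (2.69 to 95.2), 9.14-fold (2.83 to 46.9), 8.20-fold (2.51 to 42.3) and 7.88-fold (2.40 to 40.8).

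The myeloid counts with the block were 76 and 142 without HPC replicate 1, 92 and 145 without HPC replicate 2, 88 and 46 without myeloid replicate 2 and 970 and 1399 without myeloid replicate 1. They were 3330 and 3267 without 48 h replicate 1 and 3333 and 3253 without 48 h replicate 2. With the block and library-total scaling they were 568 and 453, and with background scaling 0 and 0 (edgeR; 773 and 367 at an unadjusted p under 0.05). H3K4me3 in the single myeloid library exceeded HPC at chr7:127854001-127855500 (191 against 11 reads, ratio 19.4, 10.6 to 39.4) and at chr11:120853001-120855500 (811 against 51 reads, ratio 17.7, 13.3 to 24). It also did so at chr3:94484501-94486500 (ratio 11.2), chr5:67639501-67640500 (11) and chrX:20086501-20088500 (9.77). It was lower at chr13:33575001-33577000 (8 against 266 reads, HPC 29.8-fold above, 14.9 to 69.8), chr11:118947501-118951000 (16.2-fold, 10.1 to 27.8) and chr12:115212001-115214000 (10.3-fold, 5.72 to 20.5). Of 16447 regions 342 were higher and 559 lower in the myeloid library, and 200 and 1010 when scaled by all reads of the library.

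Myeloid cells were then set against 120 h B cells. Since the time under myeloid conditions is not listed, lineage and time in culture cannot be told apart here. The distal chr18:21818001-21818500 held 104 reads over the 120 h libraries and 1 over the myeloid ones (ratio 116, 20.4 to 4625; edgeR adjusted p = 0.000416). In the same direction were chr1:6812001-6812500 (ratio 80.3, 14 to 3215), chr4:32435501-32436000 (54.6, 9.36 to 2202), chr5:102175501-102176000 (42.9, 11.5 to 361) and chr1:72763501-72764500 (42.4, 14.1 to 209). The chromosome 8 group of proximal regions was lower in myeloid cells, with log2 changes of -4.77 (SE 0.44) at chr8:124327501-124331000, -4.47 (SE 0.50) at chr8:124348001-124349000 and -4.06 (SE 0.36) at chr8:124350001-124352000. Myeloid cells exceeded 120 h B cells at the distal chr11:86965501-86966500, with 3.29 ± 0.272 against 0.070 ± 0.099 CPM (ratio 30.5, 10.1 to 150), and at chr2:164991501-164992000 (21.1, 5.52 to 179), chr9:44448501-44449000 (20.6, 5.39 to 175), chr5:39875001-39875500 (18.8, 4.90 to 161) and chr1:70794001-70794500 (18.8, 4.90 to 161). The proximal chr4:154509001-154509500 (log2 3.07, SE 0.53) and chr7:128205501-128206500 (log2 2.82, SE 0.49) were also higher in myeloid cells.

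Of 82320 H3K4me1 regions 9009 were higher and 9150 lower in myeloid cells than in 120 h B cells (edgeR), and 15280 and 14852 with the block. Of the distal regions 8209 were higher and 7307 lower. Of the proximal regions 800 were higher and 1843 lower, a direction that turned to 730 against 519 under library-total scaling. That scaling gave 9565 and 4903 in all, and scaling on background bins 265 and 215. With the block, library totals gave 16658 and 8033 and background bins 2148 and 777. Of the 16 regions the rule named, 5 lost their call without 120 h replicate 2, 4 by DESeq2 and 2 on background bins. The counts were 1544 and 3835 without 120 h replicate 2, 4749 and 3937 without myeloid replicate 2 and 5993 higher without myeloid replicate 1 (7037 lower). With the block they were 4982 and 7536 without 120 h replicate 2 and 7362 and 7015 without myeloid replicate 2. H3K4me3 was higher in the myeloid library at 960 and lower at 651 of 16447 regions, which turned to 540 and 1348 when scaled by all reads of the library. Among the regions the rule named, the myeloid library was furthest below 120 h at chr4:44988501-44990000 and chr16:16774001-16777500. The first held 90 reads at 120 h against 1 (ratio of 120 h to myeloid 71.8, 12.6 to 2868). The other held 925 against 12 reads (ratio of 120 h to myeloid 61.5, 35.1 to 120). At chr18:35773001-35774500, chr9:107183501-107186000 and chr19:41045001-41047500 the 120 h library was 38.0-fold, 37.7-fold and 30.7-fold above. The myeloid library was 34.8-fold above at chr2:78866501-78868000, 30.3-fold at chr3:94462001-94465000 and 29.9-fold at chr7:127854001-127855500.

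Changes against HPC were set side by side between the B-cell and myeloid conditions. With the block, 267 of the 305 regions higher at 48 h were also higher at 120 h, against 40.9 for independent lists of the same size. Of the 29 lower, 27 were also lower at 120 h (3.92 for independent lists), and 1 region changed in opposite directions. Between 120 h and myeloid, 233 regions were higher in both (272 for independent lists), 302 lower in both (252) and 1095 changed in opposite directions (524). Between 48 h and myeloid the counts were 9 (7.51), 4 (0.656) and 38 opposite (7.61). In 10 simulations of unchanged groups against the same HPC libraries edgeR made at most 1 call per comparison, so their shared count of 0 is fixed by the lack of calls and is no yardstick for the counts above. Without the block each shared count was 0, since edgeR called no region at 48 h or in myeloid cells against HPC. The covariance of log2 changes with the block was 0.186 for 48 h and 120 h (simulated 0.0374), -0.0225 for 120 h and myeloid (simulated 0.0375) and 0.0164 for 48 h and myeloid (simulated 0.0375). The correlations across regions were 0.571, -0.0562 and 0.0803, against simulated values of 0.494, 0.478 and 0.505. Splitting the HPC replicates leaves 1 library per part, so part of any excess may come from the shared HPC libraries. Changes that share no library correlated at r = 0.424 (48 h replicate 2 with 120 h replicate 1) and 0.0760 (48 h replicate 1 with 120 h replicate 2). In H3K4me3, 141 regions were lower in both the 120 h and the myeloid library than in HPC (29.5 for independent lists) and 34 higher in both (6.45), while 36 were lower at 120 h and higher in myeloid (18.0) and 19 the reverse (10.5). All of these share 1 HPC library, so independent lists are not the value of no change. In 10 simulations with counting error alone and that HPC library shared, 5.60 regions on average were lower in both (highest 8), 10 higher in both (highest 15) and 0 opposite, among at most 114 calls at 120 h and 135 in myeloid cells. Variation between libraries beyond counting is in neither value, so the excess is not read as a shared change.

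Whether the marks moved together was tested on distal H3K4me1 regions whose nearest H3K4me3 region lay within 100 kb. Of the distal regions that rose at 120 h, 241 had a nearest H3K4me3 region that rose and 153 one that fell, whereas of those that fell 25 had one that rose and 434 one that fell. The odds ratio was 27.3 (two-sided Fisher's exact test, p = 4.87e-75). Between myeloid cells and 120 h B cells the 4 counts were 777, 167, 266 and 622, an odds ratio of 10.9 (Fisher's exact test, p = 5.76e-119). Between myeloid cells and HPC there were no calls without the block (0 regions, edgeR), and with it the counts were 72, 41, 14 and 128, an odds ratio of 16.1 (Fisher's exact test, p = 3.28e-20). With the block the other odds ratios were 12.7 and 7.51. The 4 counts behind the 12.7, at 120 h against HPC, were 373, 324, 87 and 957. In that test 5.22% of the gains lay nearest a higher and 4.53% nearest a lower H3K4me3 region. Among regions not called these shares were 1.8% and 6.1%. The link was not rerun under another scaling of either mark, though the split of H3K4me3 calls changed with its scaling. Regions are not independent replicates and H3K4me3 comes from 1 library per group, so these p-values describe these libraries and are too small as tests of the cell states. For most changed distal regions the nearest H3K4me3 region was not called: of 3634 that rose at 120 h 6.63% had a nearest H3K4me3 region that rose, and of 3402 that fell 12.8% had one that fell, against 1.87% and 6.47% of the 44481 not called.

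**Figure D3:**
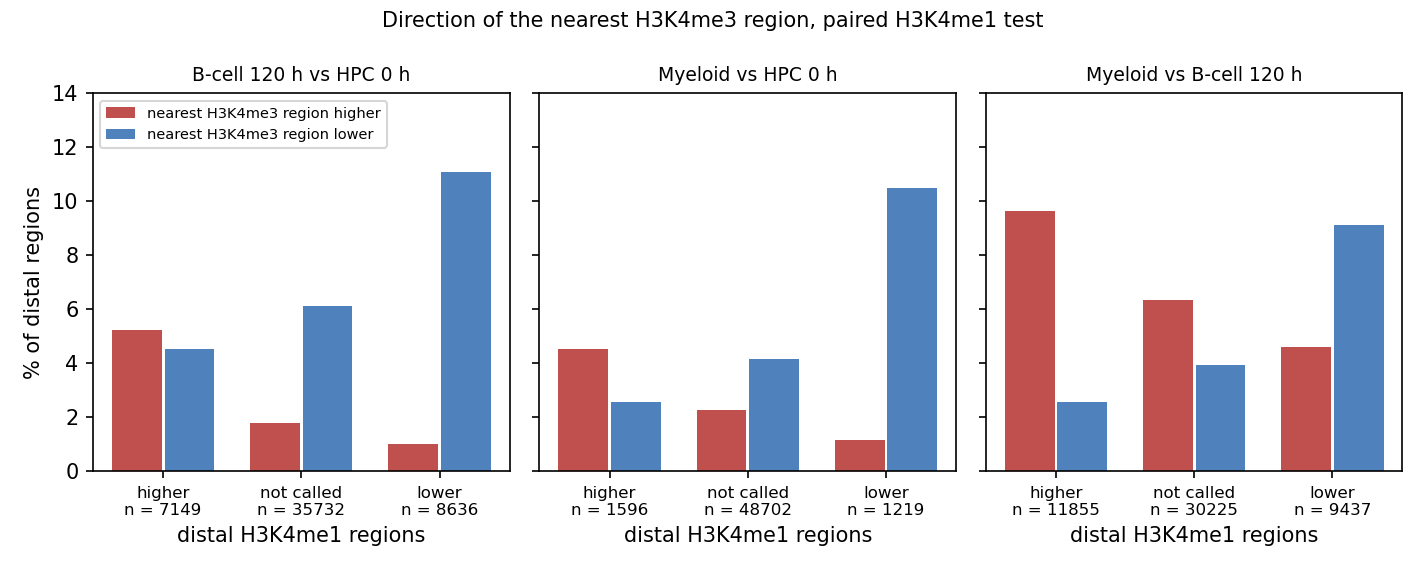
Share of distal H3K4me1 regions (y axis, %) whose nearest H3K4me3 region within 100 kb was higher (red) or lower (blue), for regions called higher, not called or called lower in the paired H3K4me1 test (x axis, with the number of regions) in 3 comparisons; no error bars are drawn, since regions are not replicates. At 120 h against HPC, 5.22% of the regions that rose lay nearest a higher H3K4me3 region against 1.01% of those that fell.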

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

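The tests of reads shared with the 120 h library and of the antibody lot were chosen only after the results they concern had been seen.

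With the replicate number as a block, 625 H3K4me1 regions were higher at 120 h and lower in myeloid cells than in HPC, a difference between groups. With the same block, 470 regions were lower at 120 h and higher in myeloid cells. Each of these also differed between myeloid cells and 120 h B cells, which was all but fixed by choosing regions called in opposite directions against the same HPC libraries. Both counts rest on the myeloid calls against HPC. Those calls were 0 and 0 without the block, and 0 and 0 on background bins with it. With the block they also depended on single libraries.

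The 48 h replicates lay at different places between HPC and 120 h: along the axis taken from the other replicate, 48 h replicate 1 had covered 6.87% of the 120 h change and replicate 2 had covered 35.3%. Depth was argued against, since the gap was 28.57 points after thinning to equal reads. The change of 48 h replicate 1 from HPC correlated at r = 0.1405 with that of replicate 2 and at -0.0211 with that of myeloid replicate 2. This difference of 0.162 in r argued against replicate 1 being a wholly unchanged HPC library. A nearly unchanged library is not excluded, since the r of 0.1405 is low. The same r between replicates was 0.697 at 120 h and 0.446 in myeloid cells. Reads of the 120 h library within 48 h replicate 2 cannot be told apart from a true difference: the excess of shared positions was 0.095 percentage points, but only 1.89% of the 120 h reads repeat a position, so the bounds set for this test were too wide to decide. A faster course of differentiation in replicate 2, which could follow from the 2 culture conditions the labels allow, stays open and untested.

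Libraries with the same replicate number deviated together. Depth was argued against, since the lowest correlation of the replicate differences was 0.2066 after thinning every library to the same read number. Thinning does not equalize enrichment. The share of reads in H3K4me1 regions was lower in replicate 1 than in replicate 2 in HPC (40.8% and 48.6%), at 120 h (36.3% and 46.8%) and in myeloid cells (37.6% and 50.7%). It was higher at 48 h (56.6% and 50.6%). Repeat reads were more frequent in replicate 1 in each group. Neither difference was tested as an explanation. The antibody lot cannot be told apart from the replicate number: a lot is given for replicate 2 alone, and the component that separates the numbers carried 17.8% of the variance. No biological explanation was tested.

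Where both were called at 120 h against HPC, distal H3K4me1 and the nearest H3K4me3 region moved alike in 675 cases and oppositely in 178. The agreement was clearer for losses of H3K4me1 (434 alike, 25 opposite) than for gains (241 and 153). The H3K4me3 calls themselves were mostly losses (867 lower, 310 higher). A regional shift of background or copy number cannot be told apart as a part of this agreement. Background bins within 50 kb moved in the same direction by 29.5% of the regions' own change for gains and 32.23% for losses, between the bounds set beforehand. Such a shift could also be H3K4me1 that spreads beyond the regions, which no test here separates from background. Regulation of promoters along with nearby enhancers upon differentiation, the biological explanation, stays open as a hypothesis.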

How the results depend on the processing

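The scalings combined with the block, the block without the 48 h libraries and the left-out libraries under the block were chosen after seeing the data. Counts are given as higher and lower; the cause of a change was not tested unless stated. No named H3K4me1 region reversed where it was tested. Of the 77 named, 66 were not tested with regions at 4-fold, 28 with windows of 1000 bp and 5 without the read shift. Of the comparisons that were tested, 1333 kept their side of the threshold in the test without the block, 125 lost it and 60 gained it. Lost were 16 of 16 on background bins without the block (1 of 16 with it) at 120 h against HPC and against 48 h. The 13 regions named at 48 h and the 16 named in myeloid cells against HPC were not called without the block. For them, kept means still not called. All 13 and all 16 also had no call on background bins with the block, which is scored as kept. The 1333 also include settings that left out a library outside the comparison, which acts only through the shared spread and scaling. At 120 h against HPC, 16 of 16 kept their call without either myeloid library. The 1333 against 125 is therefore no measure of how stable the calls are. Of the other values 243 stayed and 135 moved. Under scaling by library total and on background bins, the median log2 change over regions became -0.22 and -0.35 at 120 h against HPC, 0.18 and 0.64 at 48 h against HPC, and -0.02 and 0.10 in myeloid cells against HPC. Between 120 h and 48 h it became -0.40 and -0.99, and between myeloid and 120 h 0.20 and 0.46. Leaving out a library leaves 1 in its group, assumed to vary like the others. The gene lists with the body of the gene alone or with the block were not run, for want of an annotation of mm8. No paired analysis was possible for H3K4me3 because each group has 1 library.

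With the replicate block the counts became 11038 and 11140 (120 h against HPC, from 5100 and 4285), 305 and 29 (48 h against HPC, from 0 and 0), 6978 and 7257 (120 h against 48 h, from 1809 and 1441), 2027 and 1861 (myeloid against HPC, from 0 and 0) and 15280 and 14852 (myeloid against 120 h, from 9009 and 9150). The 13 regions named at 48 h and the 16 named in myeloid cells against HPC were picked for passing with the block, so their gain with the block is fixed by that choice. The other gains among the 60 came with the block and library-total scaling (13 and 16) and with DESeq2 (1 and 1). The block changed the call of no other named region. Under the block 200 distal regions changed the same way as the nearest H3K4me3 region in myeloid cells against HPC, from 0. Shared changes went from 0 to 267 higher, 27 lower and 1 opposite (48 h and 120 h), 233, 302 and 1095 (120 h and myeloid) and 9, 4 and 38 (48 h and myeloid).

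Scaling by library total gave 2198 higher at 120 h against HPC, 686 and 4936 at 120 h against 48 h, and 4903 lower in myeloid against 120 h. TMM over background bins gave 0 and 0 at 120 h against HPC (edgeR; unadjusted 1525 and 5565; DESeq2 3772 and 2598), 0 and 0 at 120 h against 48 h (unadjusted 226 and 17410), and 265 and 215 in myeloid against 120 h. The biological coefficient of variation was 0.446 with that scaling against 0.192. Its factors for replicates 1 and 2 were 1.24 and 0.923 (HPC), 0.672 and 0.879 (48 h), 1.38 and 1.01 (120 h) and 1.36 and 0.782 (myeloid). In each group the library with the lower share of reads in H3K4me1 regions had the larger factor. This scaling thus keeps differences in enrichment between the replicates. DESeq2 gave 2598 lower at 120 h against HPC, 2 higher at 48 h, 41 and 74 in myeloid against HPC and 5495 higher in myeloid against 120 h. It gave an adjusted p to 67956 regions at 120 h against HPC, 59976 at 120 h against 48 h, 26460 in myeloid against HPC and 80724 in myeloid against 120 h. A named region without an adjusted p from DESeq2 was scored as not called. Regions at 4-fold, fewer by construction, gave 2184 higher and 2896 lower at 120 h against HPC, a direction turned from 5100 and 4285. They gave 455 and 1002 at 120 h against 48 h, turned from 1809 and 1441. In myeloid against 120 h they gave 5234 and 4494, turned from 9009 and 9150. Which direction held more regions thus depended on the region threshold. Thinned libraries gave 2660 lower at 120 h against HPC and 883 lower at 120 h against 48 h, the loss that fewer reads bring.

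The block with library-total scaling gave 4796 and 12729 at 120 h against HPC, 392 and 8 at 48 h, 2055 and 15365 at 120 h against 48 h, 568 and 453 in myeloid against HPC and 16658 and 8033 in myeloid against 120 h. The block with background bins gave 134 and 40 at 120 h against HPC, 53 and 4282 at 120 h against 48 h and 2148 and 777 in myeloid against 120 h. The block without the 48 h libraries gave 12605 and 12858 at 120 h against HPC, 3349 and 3232 in myeloid against HPC and 16791 and 16230 in myeloid against 120 h.

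Leaving out 1 library in turn, counts ranged from 694 to 5187 higher and 158 to 4229 lower (120 h against HPC), 22 to 1882 and 1 to 1399 (120 h against 48 h), 0 to 1 lower (myeloid against HPC, 0 higher) and 1544 to 8729 and 3835 to 8988 (myeloid against 120 h). For H3K4me3, 8-fold regions gave 464, 430 and 713 changed regions (120 h against HPC, myeloid against HPC, myeloid against 120 h, from 1177, 901 and 1611), a ratio of 4 gave 283, 179 and 457 by construction, and windows of 1000 bp gave 741 and 590 in the first 2. Sets at 8-fold held 5290, 11512, 5667 and 5623 regions (HPC, 48 h, 120 h, myeloid), with overlaps of 35.05% (120 h with HPC), 42.91% (myeloid with HPC) and 27.85% (myeloid with 120 h). Thinning gave 59.33%, 62.79% and 44.91%, and all reads kept 61.91% and 66.14% for the first 2.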

Other observations

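The analyses in this part, of flanks, region sets, clusters and 48 h values, were not in the design and were chosen after the data had been seen.

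The flanks of H3K4me3 regions, 2 kb on either side, were measured for H3K4me1. At the 310 H3K4me3 regions higher at 120 h than in HPC, flanking H3K4me1 changed by log2 0.67 (replicate 1) and 0.82 (replicate 2), at the 867 lower regions by -0.31 and -0.23, and at the 15270 within 2-fold by 0.11 and 0.18. In myeloid cells against HPC the values were 0.17 and 0.20 at 342 higher regions, -0.26 and -0.23 at 559 lower ones and -0.06 and 0.00 at the rest. Between myeloid cells and 120 h B cells they were 0.30 and 0.25 at 960 higher regions, -0.68 and -0.78 at 651 lower ones and -0.16 and -0.18 at those within 2-fold. Over the H3K4me3 regions themselves H3K4me1 changed by 0.02 and 0.18 at the 867 regions lower at 120 h (0.22 and 0.28 at the 310 higher, 0.14 and 0.30 within 2-fold) and by -0.18 and -0.13 at the 960 higher in myeloid cells than at 120 h (-0.19 and -0.24 at the 651 lower, -0.20 and -0.22 within 2-fold). No test was run on these medians. Distal regions that rose at 120 h (4216) were in the HPC set in 25.1% and in the 48 h set in 45.8% of cases, against 31.7% and 39.8% of all 59307 distal regions. Those that fell (3930) were in the HPC set in 65.9%, in the 48 h set in 53.9% and in the myeloid set in 61.2% (21.6% of those that rose, 31.9% of all distal regions). The HPC libraries define these changes and the HPC set alike, so the HPC shares are fixed in part by how the regions were chosen.

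Distal regions that changed were counted in blocks of 500 kb. In 120 h against HPC, 18 of 64 regions rose in chr12:80500001-81000000 and 18 of 47 in chr6:120500001-121000000, against a highest count of 17 in 1000 permutations within chromosomes. Of those that fell, 19 of 58 lay in chr13:95000001-95500000, 15 of 36 in chr4:152500001-153000000, 15 of 30 in chr5:132500001-133000000 and 14 of 34 in chr14:32500001-33000000 (highest of the permutations 13). With the block, chr6:120500001-121000000 (22 regions, highest 23) and the last 2 of these (24 each, highest 24) no longer exceeded the permutations. Between myeloid cells and 120 h B cells, 26 of 35 regions were lower in myeloid cells in chr12:114500001-115000000 and 22 of 42 in chr11:44500001-45000000 (highest 19). In the other direction no block exceeded the permutations (20 against a highest of 22, and 29 against 29 with the block). The permutations take no account of neighbouring regions that may be parts of 1 marked stretch. A count above them is therefore not evidence that separate regions changed together. At 48 h, regions that rose by log2 1 or more at 120 h in the other replicate had changed by -0.03 in replicate 1 (n = 5034, 1.08 at 120 h) and by 0.47 in replicate 2 (n = 4637, 1.18 at 120 h). Those that fell had changed by -0.10 (n = 5284, -0.79 at 120 h) and -0.27 (n = 4743, -0.85 at 120 h).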
